A study of Mus musculus with 16 samples.

How the data were processed

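Retroperitoneal fat of gonadectomised mice was profiled on 16 Affymetrix arrays, 8 from males and 8 from females. In each sex 2 arrays came from vehicle-treated mice and 1 array from mice injected under the skin with 0.1 mg of dihydrotestosterone (DHT), the potent androgen made from testosterone, at each of 6 times before necropsy (1, 3 and 6 h, here called early, and 12, 18 and 24 h, called late). The labels describe the vehicle samples with a time of 24 h, which was read as the time since the vehicle injection, although no label says so. The fat of all mice of a group was collected together, per the labels' protocols, so that an array may hold RNA pooled from several animals. Nothing in the labels says that the 2 vehicle arrays of a sex came from separate animals, and p-values then measure only the spread between these samples, which may be technical. Replicate numbers were given in accession order and pair no samples.

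The deposited values are linear signal intensities, 1 per probe set and array, made by the authors with MAS5, per the submitters' processing notes. The MAS5 version is not given in the sources used here. Every array had the same mean signal of 500 after trimming 2% of the probe sets at each end, so that levels are relative to the whole array. A gene that changes together with many others is therefore measured against a shifted scale. Median signals lay between 184 and 220 on the 16 arrays, and detection calls were not used here. The number of arrays limits the precision, and low signals hold a larger share of background.

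The arrays hold 12488 probe sets, of which 66 are controls. The platform annotation listed 11251 of them and left 1237 unnamed here. Of the listed probe sets 10855 had 1 gene symbol and 396 had several, and no gene was named from the latter. The Entrez identifiers of 10839 probe sets matched a table of gene names of the mouse assembly GRCm38, and no symbol differed from it. For each of 8251 genes the probe set with the highest mean log2 signal was used, which was a choice among several for 2073 genes. Genes under the 40th percentile of mean signal, a signal of 116.03, were left out, and 5686 genes were tested. For some of the named genes the values of other probe sets are given beside the gene.

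Signals were analysed as log2(signal + 16), so that fold changes understate the change of genes with low signal. limma (version 3.58.1, in R 4.3.3) was fitted with sex and time as factors to all 16 arrays, with eBayes and a trend in the mean. This leaves 8 residual degrees of freedom, and the residual spread holds sex differences of the response at each time as well as array noise. Contrasts were each DHT time against vehicle (2 arrays against 4), the mean of the 6 times against vehicle (12 against 4), 12, 18 and 24 h against 1, 3 and 6 h (6 against 6), and female against male (8 against 8). A moderated F test took the 6 times together. A second model with a sex by DHT term (7 residual degrees of freedom) gave the sex difference of the mean response. All limma tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 5686 genes, with a threshold of 0.05. Male and female fold changes at matched times, each against the vehicle arrays of the same sex, were correlated across genes. Their mean correlation was set against all 720 pairings of male with female times in an exact one-sided permutation test.

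The 30 gene lists were: classical targets of androgen and glucocorticoid response elements, steroid receptors and steroid metabolism, fatty acid synthesis, triglyceride synthesis and fatty acid uptake, lipolysis, fatty acid oxidation, oxidative phosphorylation, tricarboxylic acid cycle, glycolysis and glucose uptake, cholesterol synthesis, adipocyte differentiation and adipokines, brown and beige adipocyte, immediate early genes, circadian clock, cell cycle, insulin and IGF signalling, extracellular matrix, unfolded protein response and heat shock, acute phase and inflammation, and interferon response. The others were markers of macrophages, T cells, B cells, endothelium, smooth muscle, mesothelium, skeletal muscle, kidney, adrenal and erythrocytes, which are other cells that dissected fat may hold. Some genes belong to several lists. An older symbol shared by several genes was not used to resolve list members, a rule set after the values were seen. The 28 lists with at least 5 tested members were compared with all other genes by limma's camera with an inter-gene correlation of 0.01, and again with an estimated correlation, adjusted over the lists of a contrast. Members were also tested with adjustment over the list alone.

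Genes were named by a rule. For DHT over all times, late against early times and female against male, the 10 largest rises and 10 largest falls among genes past the threshold were named. For each time these were the 6 and 6 largest with both sexes moved the same way, and for the sex difference of the response the 5 largest each way. Where no gene passed, the 3 smallest p-values in each direction were named as not passing. For each list described, up to 4 members with the smallest p were named. Lep, Adipoq, Pparg and Fkbp5 were always to be named, with a further gene that is not reported here, and Xist and genes of the Y chromosome served to check the sex labels. The models, lists, naming rule and first set of other settings were fixed before the data were examined. One vehicle array proved rich in muscle transcripts, and all results were computed again from the other 15 arrays. That fit (7 residual degrees of freedom), and the genes named because they passed only in it, were chosen after the values were seen.

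The first set of other settings, fixed together with the models, held a pseudocount of 1 or 64, no filter, a filter at the 60th percentile, quantile normalization, all probe sets tested separately, eBayes without a trend, leaving out each array, a separate mean for each of the 14 groups of sex and time, the 6 times as replicates, the 4 vehicle or the 12 DHT arrays alone, leaving out each time, and the estimated correlation. Settings added after the values were seen were the 15 arrays, the level of the antisense control probe sets as a covariate, both together, and the 15 arrays with separate means or with the 6 times as replicates. That level is the mean log2 signal of the Gapdh and beta-actin control probe sets whose names end in _st. The word antisense serves here only as a label for them.

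The models were tested on simulated data in which 200 of the 5686 genes were changed by known amounts. The simulated noise had each gene's residual spread but was independent between genes and arrays, with no array standing apart. The shares recovered may therefore not hold for the real arrays. For DHT over all times, 72% of genes changed by a log2 of 1 and 97% of those changed by 2 were recovered with 16 arrays. The shares were 30% and 76% for 6 h alone, 66% and 96% for late against early times, 80% and 97% for female against male, and 10% and 67% for the sex difference of the response.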

Results

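Messenger RNA levels in retroperitoneal fat, a visceral depot behind the abdominal cavity, were measured on 16 single-colour arrays. The mice had been gonadectomised, so that the injected DHT was set against a low level of gonadal androgen. Each sex had 8 arrays, of which 2 came from vehicle-treated mice and 1 from each of the 6 times after DHT. The question the design poses is how the adipose transcriptome of males and females responds to an androgen over 24 h. Values after ± are limma's standard errors for log2 changes of single genes and standard deviations (SD) for signals. For means over several genes they are standard errors from ordinary least squares.

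The sex labels were checked first. Signals of Xist, the RNA that coats the inactive X chromosome, were 1315 ± 379 (SD, n = 8) in females and 29.6 ± 21.0 (SD, n = 8) in males. The Y-linked gene Eif2s3y had signals of 23.0 ± 14.4 in females and 254 ± 87.9 in males (SD, n = 8 each). Uty, another Y-linked gene, had 23.7 ± 20.3 in females and 104 ± 30.3 in males (SD, n = 8 each), with a slight overlap between the highest female (66.6) and the lowest male (63.4). Kdm5d was low on all arrays and overlapped between the sexes, and Ddx3y was not analysed here. No array went against its label for Xist or Eif2s3y.

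Male vehicle replicate 2 differed from all other arrays in its cell type markers. All 19 skeletal muscle genes were higher on it than on each of the other 15 arrays, with a median ratio of 9.55 to the mean of the 7 other male arrays. Ryr1, the calcium release channel of muscle, had a signal of 22658 there and 612 ± 220.0 (SD, n = 7) on the other male arrays. The signal of Myh1, a fast myosin heavy chain, was 13263 there and 355 ± 316 (SD, n = 7) on those arrays. These genes had the largest ratios, which ranged from 3.30 to 37.3 over the list. Muscle transcripts were also present on the other male arrays, with signals of 8860 ± 2303 for Acta1 and 8694 ± 2282 for Myl1 (SD, n = 7). All 16 macrophage genes were lower than on each other array (median ratio 0.224 to the same mean), as were 13 of 18 adipocyte genes (0.490 over all 18). Adipoq, which encodes the fat hormone adiponectin, had a signal of 1946 there and 25923 ± 3611 (SD, n = 7) on the other male arrays. Across genes, this array correlated with the others at r = 0.606 to 0.701, while the other 15 correlated with each other at 0.877 to 0.978 (genes are not independent replicates). Its Xist signal lay within the male range and its Eif2s3y signal was 426. Since it is 1 of 4 vehicle arrays, results are given for all 16 arrays, as planned, and many also for the 15 arrays without it.

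**Figure D1:**
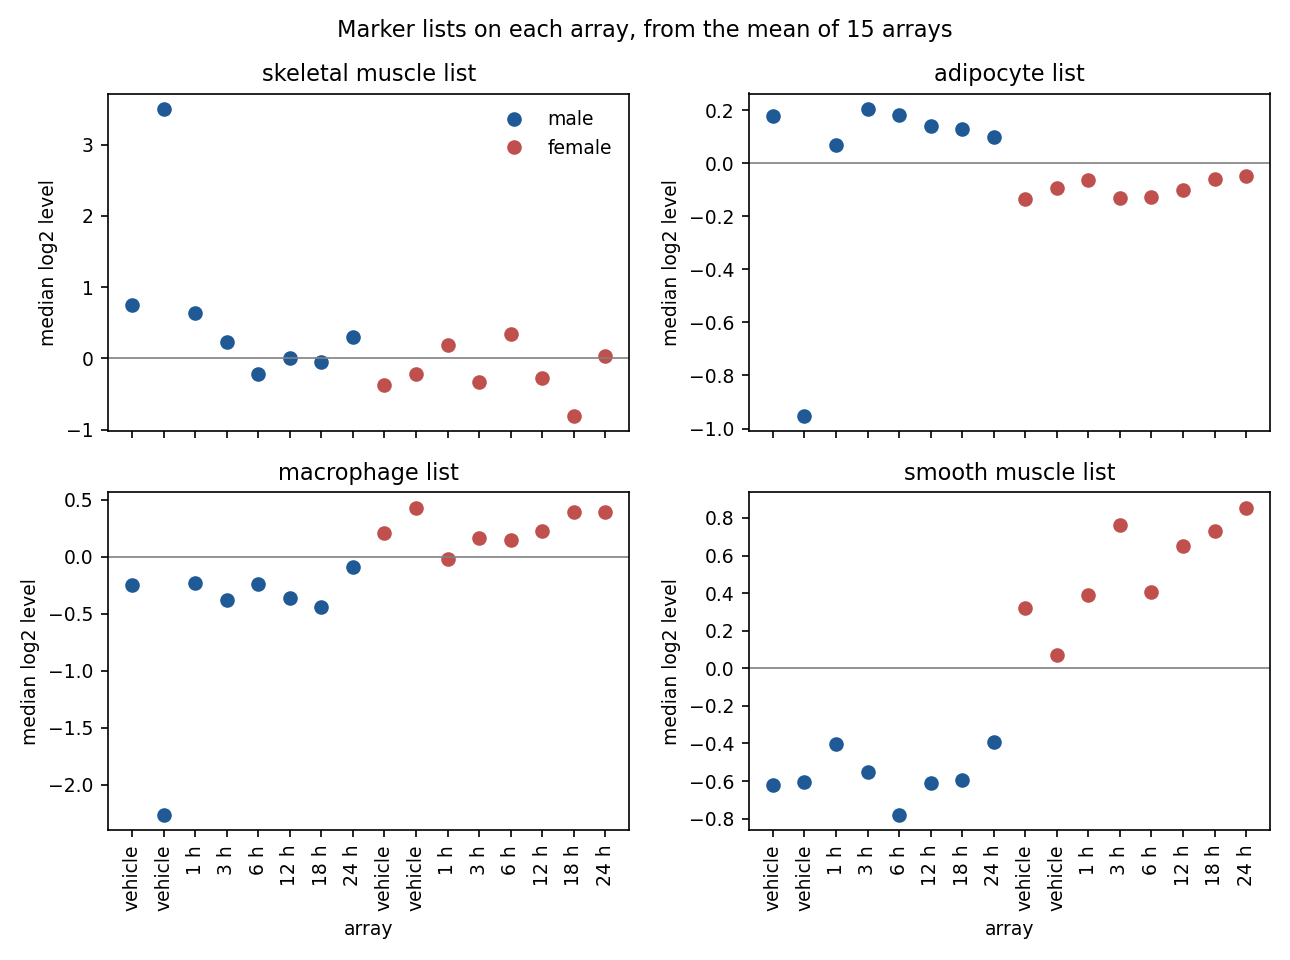
Median log2 level of 4 marker lists (skeletal muscle, adipocyte, macrophage and smooth muscle) on each of the 16 arrays, relative to the mean of the 15 arrays without male vehicle replicate 2. That array lies at 3.50 for skeletal muscle, -0.95 for adipocyte and -2.26 for macrophage genes.

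The response to DHT was first taken over all times, with the 12 DHT arrays set against the 4 vehicle arrays. The 4 genes that passed all rose, and all belong to the list of classical targets of androgen and glucocorticoid response elements, the DNA sites linked to these hormones. Mt2, which encodes a metal-binding metallothionein, rose 3.10-fold (log2 1.63 ± 0.20), from 1503 ± 402 (SD, n = 4) to 5208 ± 2508 (SD, n = 12). Gadd45g, a stress-inducible growth arrest gene, rose 2.71-fold (log2 1.44 ± 0.15), from 351 ± 32.6 to 1050 ± 409. Fkbp5, a co-chaperone of steroid receptors, rose 2.60-fold (log2 1.38 ± 0.18), from 626 ± 244 to 1719 ± 733. Errfi1, a feedback inhibitor of the EGF receptor, rose 1.73-fold (log2 0.79 ± 0.12), from 795 ± 77.8 to 1408 ± 265. The adjusted p from limma was 0.0116 for Mt2, 0.00436 for Gadd45g, 0.0125 for Fkbp5 and 0.0401 for Errfi1. Signals lay above the mean vehicle signal of the same sex in 6 male and 6 female DHT arrays for Gadd45g, Fkbp5 and Errfi1, and in 6 male and 5 female arrays for Mt2. With 15 arrays the same 4 genes rose, by 1.40 ± 0.14, 1.36 ± 0.15, 1.52 ± 0.16 and 0.73 ± 0.11 in the order Mt2, Gadd45g, Fkbp5 and Errfi1. Cdkn1a, the cell cycle inhibitor p21, then also passed at 0.87 ± 0.14 (adjusted p from limma = 0.0392; 1.08 ± 0.17 and 0.0657 with 16 arrays), but its other probe set gave -0.04 with 16 arrays.

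Single arrays decided some of these calls. Mt2 (1.66) and Errfi1 (0.78) did not pass without female vehicle replicate 1, and Fkbp5 (1.43) and Errfi1 (0.83) did not pass without female vehicle replicate 2, which left 2 genes each time. Without male vehicle replicate 1, Fkbp5 (1.39) and Errfi1 (0.83) did not pass and Inmt did (1.36 ± 0.15). The muscle-rich array is then the only male vehicle array, as in each later result without male vehicle replicate 1. Errfi1 passed only with all 16 arrays or without male vehicle replicate 2, and its log2 change was 0.76 to 0.83 when any other array was left out. When the 6 times were treated as replicates of a single DHT group, limma called 0 genes with 16 arrays (638 at an unadjusted p under 0.05) and 0 with 15 (174).

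**Figure D2:**
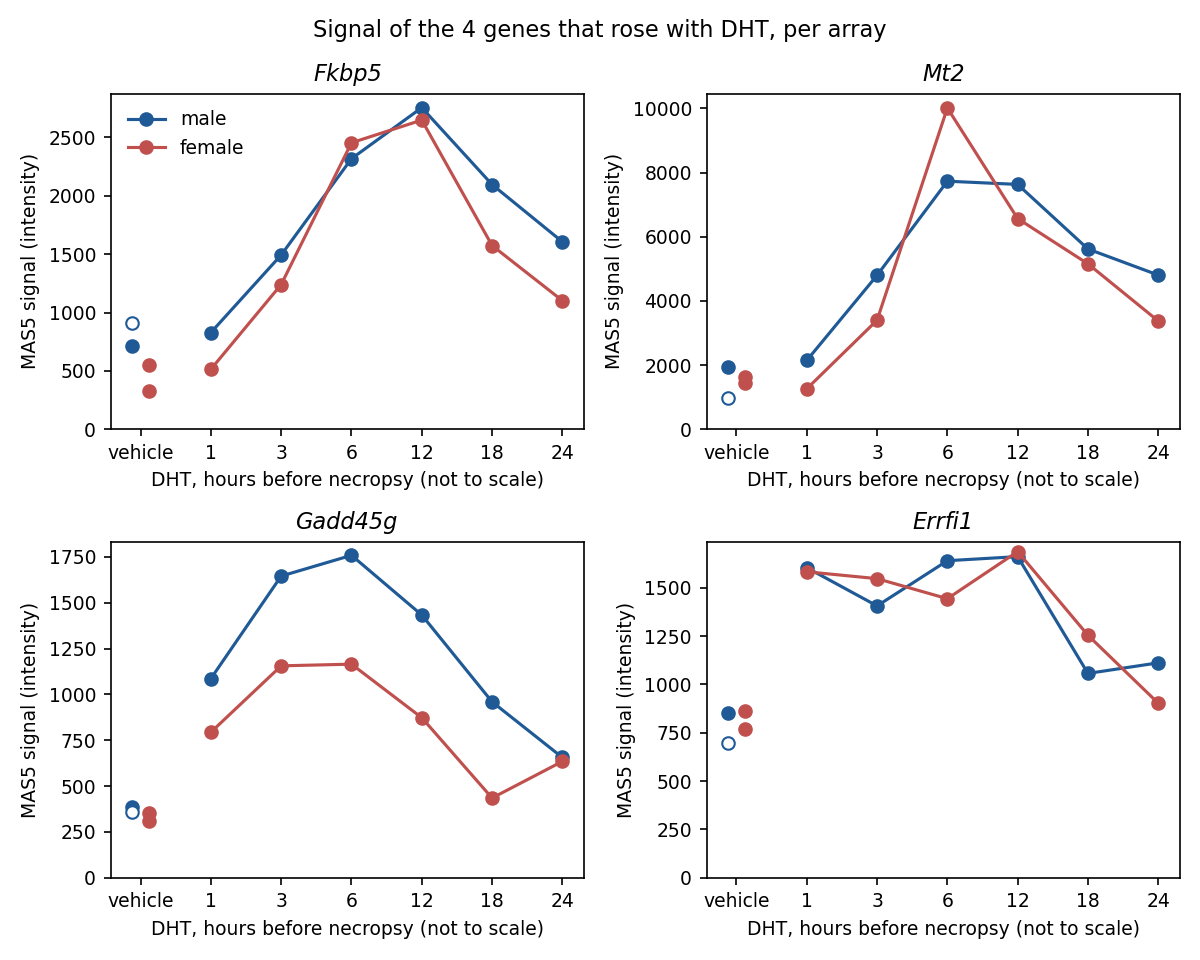
Signal of Fkbp5, Mt2, Gadd45g and Errfi1 on each array, with males in blue and females in red, for vehicle (V; the open circle is male vehicle replicate 2) and for 1 to 24 h after DHT (hours not to scale). Mt2 reached 10009.8 in the female and 7729 in the male array at 6 h.

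As a group, 17 of the 22 tested hormone response element genes had positive log2 changes over all times (mean 0.52). Of these, 4 rose over all genes tested and 8 rose when adjusted over the list alone, and none fell. The list ranked above other genes by camera in limma (adjusted p = 6.034e-08, and adjusted p = 0.00492 with an estimated correlation). With 15 arrays, 20 of 22 were positive (mean 0.49), 5 rose over all genes and 10 rose adjusted over the list alone (adjusted p = 6.216e-19 by camera, and 0.000522 with an estimated correlation).

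The other 12 lists that camera called with 16 arrays were not called without the muscle-rich vehicle array, and none kept its call with an estimated correlation (adjusted p = 0.473 to 0.503). Skeletal muscle genes (mean -0.87), oxidative phosphorylation (-0.20) and the tricarboxylic acid cycle (-0.14) ranked lower. Fatty acid synthesis (0.68), triglyceride synthesis (0.45), lipolysis (0.70), cholesterol synthesis (0.40), adipocyte genes (0.42), extracellular matrix (0.34), acute phase (0.47), interferon response (0.35) and macrophage genes (0.43) ranked higher. No member of these 12 lists passed, and adjusted over the list alone 1 adipocyte gene did. Examples that did not pass were Mb, the muscle oxygen store myoglobin (-1.75 ± 0.73), Lipe, the hormone-sensitive lipase (1.09), and Scd1, a fatty acid desaturase (0.75). With 15 arrays these 12 means lay between -0.07 and 0.11. Smooth muscle genes were called with 15 arrays (mean 0.22, adjusted p = 0.0121 by camera in limma, and adjusted p = 0.224 with an estimated correlation). In that list Mylk (0.44) and Acta2 (0.41), both of the contractile apparatus, passed adjusted over the list alone.

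The remaining 15 lists were not called with 16 arrays, with camera's adjusted p between 0.0573 and 0.835. Their means were 0.44 for steroid receptors and metabolism, 0.05 for fatty acid oxidation, -0.17 for glycolysis, -0.01 for brown adipocyte genes, 0.14 for immediate early genes and -0.28 for the circadian clock. Further means were 0.08 for the cell cycle, 0.10 for the unfolded protein response, 0.12 for T cells, 0.18 for B cells, 0.13 for endothelium, 0.15 for adrenal and 0.34 for erythrocyte genes. Signs differed for smooth muscle (mean -0.08, median 0.02, ranked up) and for insulin and IGF signalling (mean 0.14, median 0.07, ranked down). Lep, the satiety hormone leptin (0.59), Adipoq (0.90) and Pparg, the master regulator of fat cells (0.86), did not pass (adjusted p from limma = 0.630 each). Their values were -0.038, -0.039 and 0.0018 with 15 arrays.

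Each time was next compared with the vehicle arrays, with 2 DHT arrays against 4. Fkbp5 and Mt2 were highest at 6 and 12 h. Fkbp5 had log2 changes of 0.15, 1.19, 1.99, 2.17, 1.60 and 1.16 (each ± 0.27) at the 6 times in order, and Mt2 0.17, 1.46, 2.58, 2.27, 1.87 and 1.45 (each ± 0.30). Gadd45g was 1.37 at 1 h, 1.93 and 1.98 at 3 and 6 h, and 0.86 and 0.85 at 18 and 24 h (each ± 0.22). Errfi1 was 0.99 at 1 h, 1.06 at 12 h and 0.33 at 24 h (each ± 0.18).

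At 1 h no gene passed in limma with 16 or 15 arrays (136 and 232 genes at an unadjusted p under 0.05). The smallest p among higher genes were those of Gadd45g (adjusted p = 0.365), Errfi1 (0.397) and Cebpd, a transcription factor of early fat cell differentiation (0.87 ± 0.19). Among lower genes they were those of Actb (-2.35), Klf13 (-2.69) and Nipsnap2 (-1.38), none of which passed. Both 1 h arrays also had low levels of the antisense control probe sets (log2 6.71 in the male and 6.75 in the female array, 7.64 to 9.14 on vehicle arrays). These controls include probe sets of beta-actin, the product of Actb. Without the female 1 h array 1 gene passed, Pnmt, which makes adrenaline (-2.71), whose signal was 45.1 in the male 1 h array and 299 to 581 on the other 15. Immediate early genes, the transcription factors that cells switch on within minutes of a stimulus, were called by camera with 16 arrays (mean 0.23, adjusted p = 0.0372, and adjusted p = 0.705 with an estimated correlation).

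At 3 h Gadd45g rose 3.81-fold (adjusted p = 0.0135 in limma) and was the only gene that passed with 16 arrays, and with 15 (1.85, adjusted p = 0.00826). It did not pass when male vehicle replicate 1, female vehicle replicate 1 or either 3 h array was left out (0 genes each in limma, 50 to 224 at an unadjusted p under 0.05). At 6 h Mt2 rose 5.97-fold, Fkbp5 3.98-fold and Gadd45g 3.95-fold (adjusted p = 0.00694, 0.0178 and 0.00694 in limma). Leaving out the male or the female 6 h array gave 0 genes in limma (41 and 81 unadjusted), and Fkbp5 did not pass at 6 h without male vehicle replicate 1, female vehicle replicate 2 or any of the 18 and 24 h arrays (2 genes each). With 15 arrays 5 genes passed at 6 h, the same 3 with Cdkn1a (1.41 ± 0.19) and Cebpd (1.15 ± 0.18). At 12 h Mt2 rose 4.81-fold, Fkbp5 4.50-fold and Gadd45g 3.10-fold (adjusted p = 0.0235, 0.0229 and 0.0235 in limma), and Errfi1 also passed with 15 arrays (1.00 ± 0.15). Gadd45g did not pass at 12 h without male vehicle replicate 1 or any of the 1 and 6 h arrays. limma called 0 genes at 12 h without the male 3 h, female 3 h or female 12 h array (121, 121 and 78 unadjusted), and 1 (Fkbp5, 1.96) without female vehicle replicate 1. Without the male 12 h array none of the 3 passed, and Cela2a (5.64), Cel (4.12) and Reg1 (3.34) did, which are genes of the exocrine pancreas with high signals on the female 12 h array. Both sexes moved the same way for Mt2, Fkbp5, Gadd45g, Errfi1, Cdkn1a and Cebpd. With a separate mean for each sex and time, limma called 0 genes at 3, 6 and 12 h (22, 23 and 33 at an unadjusted p under 0.05).

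At 18 and 24 h no gene passed with 16 arrays in limma (289 and 129 genes at an unadjusted p under 0.05). Mt2 (1.87), Fkbp5 (1.60) and Inmt, a methyltransferase (1.74), had the smallest p among higher genes at 18 h (adjusted p = 0.173 each), and Naa40 (-1.22), Zdhhc6 (-0.94) and Rassf1 (-1.15) among lower genes (0.703). At 24 h they were Inmt (1.48), Mt2 (1.45), Fkbp5 (1.16), Ncan (-1.20), Sf3a2 (-0.72) and Sprr1a (-1.45), with an adjusted p of 0.930 each. Without male vehicle replicate 2, Mt2 (1.64 ± 0.20) and Fkbp5 (1.74 ± 0.23) passed at 18 h. At 24 h Lrg1, a secreted acute phase glycoprotein, then passed at 1.07 ± 0.14 (adjusted p = 0.0257 in limma; 1.62 ± 0.49 and 0.930 with 16 arrays). Without male vehicle replicate 1, Inmt was the 1 gene that passed at 18 h (adjusted p = 0.0121 in limma) and at 24 h (1.75 ± 0.22, 0.0437). In that fit the muscle-rich array was the only male vehicle array.

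The hormone response element list had means of 0.42, 0.54, 0.73, 0.64, 0.46 and 0.34 at the 6 times in order. Camera in limma called it at each time (adjusted p = 3.13e-05, 9.854e-08, 1.487e-11, 1.231e-08, 0.000145 and 0.00477). With an estimated correlation the adjusted p was 0.0190, 0.00525, 0.00127, 0.00358 and 0.0355 up to 18 h, and 0.192 at 24 h. Over all genes 0, 1, 3, 3, 0 and 0 of the 22 members rose, and adjusted over the list alone 4, 6, 7, 8, 4 and 3. With 15 arrays the means were 0.38, 0.51, 0.70, 0.61, 0.42 and 0.31, and 0, 1, 5, 4, 2 and 0 members rose over all genes.

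Other lists were called at single times with 16 arrays, where the muscle-rich array is 1 of the 4 vehicle arrays. Skeletal muscle genes had means of -0.41 at 1 h to -1.30 at 18 h, oxidative phosphorylation -0.16 to -0.26, extracellular matrix 0.28 to 0.43, and macrophage genes 0.34 to 0.64 from 3 h on. Camera called 12, 12, 10, 9, 12 and 10 lists at the 6 times, and with an estimated correlation none of those other than the hormone list (adjusted p = 0.425 to 0.764). With 15 arrays the calls were 2, 2, 2, 2, 5 and 4. Besides the hormone list these were skeletal muscle at 1 h (0.40), smooth muscle at 3 h (0.28), interferon response at 6 h (0.20) and fatty acid synthesis at 12 h (-0.22). At 18 h they were cell cycle (0.13), extracellular matrix (0.15), B cell (0.36) and skeletal muscle genes (-0.50), and at 24 h extracellular matrix (0.17), macrophage (0.16) and smooth muscle genes (0.33). The adjusted p of these calls with an estimated correlation lay between 0.174 and 0.975.

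The F test over the 6 times called 3 genes with 16 arrays and 5 with 15 in limma (54 and 208 at an unadjusted p under 0.05). These were Fkbp5, Gadd45g and Mt2 (adjusted p from limma = 0.0405 each), joined by Hp and Lrg1 with 15 arrays (0.0102 each). Its count was 0 when any of 12 arrays was left out (40 to 87 at an unadjusted p under 0.05), 1 (Inmt) without male vehicle replicate 1, and 1 (Gadd45g) without the male or female 18 h array. The times share the same vehicle arrays, so that a low or high vehicle value moves all of them.

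Late times (12, 18 and 24 h) were compared with early times (1, 3 and 6 h), 6 arrays against 6. No gene passed with 16 arrays in limma (146 at an unadjusted p under 0.05). The smallest p among genes higher late were those of Inmt (1.04 ± 0.20), Actb (1.53) and Gas1 (0.51), and among genes lower late those of Brox (-0.63), Gadd45g (-0.65) and Cebpd (-0.56), with an adjusted p of 0.9996 each. Without male vehicle replicate 2, which enters only through the shared spread, 2 genes passed and both rose. These were Lrg1 (0.81 ± 0.09) and Hp, the haemoglobin-binding acute phase protein haptoglobin (0.63 ± 0.07; adjusted p from limma = 0.00398 each). Early and late arrays also differed in a technical measure, the level of the antisense control probe sets. It was low (6.38 to 6.75) on 4 of the 6 early arrays and 8.68 to 9.96 on the 6 late arrays. With that level as a covariate and 15 arrays Lrg1 alone passed late against early (0.93 ± 0.12, adjusted p from limma = 0.0345). Hp did not pass (0.68 ± 0.10, 0.0938), since its standard error grew while its change did not shrink. With 16 arrays and the covariate neither passed (0.50 ± 0.48 for Lrg1 and -0.17 ± 0.91 for Hp). Camera called 0 lists with 16 arrays (adjusted p = 0.187 for the acute phase, macrophage and skeletal muscle lists). With 15 arrays it called acute phase (mean 0.17, 1 member rose, 2 adjusted over the list alone), macrophage (0.12) and skeletal muscle genes (-0.30). The adjusted p of these 3 was 0.0184, 0.0184 and 0.000979, and with an estimated correlation the adjusted p was 0.812 each. The hormone list had a mean of -0.08, and Gadd45g and Cebpd fell adjusted over the list alone.

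Females were compared with males across all times, 8 arrays against 8. Camera in limma ranked the lists of the extracellular matrix and of smooth muscle higher in females (18 of 29 and 7 of 10 genes passed) and those of fatty acid oxidation and of brown fat lower (5 of 20 and 1 of 5). With an estimated correlation the adjusted p was 0.0574, 0.0165, 0.0546 and 0.0546, so that of these 4 the smooth muscle list alone kept its call with 16 arrays. limma called 327 genes, 263 higher and 64 lower in females (1134 at an unadjusted p under 0.05). At least 2-fold, 104 were higher and 10 lower. For 165 of the higher and 22 of the lower genes no female value overlapped a male value, which chance gives for 0.0155% of genes in either direction. With 15 arrays 943 genes passed, 502 higher and 441 lower, among them all 327, so that the excess of higher genes was much smaller. At least 2-fold, 98 were then higher and 27 lower, and 222 higher and 155 lower genes did not overlap (0.0311% by chance). The count fell to 197 without the female 6 h array, 200 without the male 6 h array, 209 without the male 12 h, female 12 h or male 18 h array, 210 without the female 18 h array and 215 without the male or female 3 h array.

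The largest rises apart from Xist (log2 4.98 ± 0.29) were those of Mmp12 and Tnc. Mmp12, an elastase of macrophages, had signals of 2843 ± 369 in females and 167 ± 123 in males (log2 4.15 ± 0.21, adjusted p from limma = 1.102e-06). Tnc, the matrix protein tenascin C, had 2184 ± 531 and 120.0 ± 40.9 (4.03 ± 0.21, 1.102e-06). Cnn1, the smooth muscle protein calponin, had 483 ± 156 and 22.7 ± 12.5 (3.69 ± 0.22). Its male signal was near those of the Y-linked genes Eif2s3y (23.0) and Uty (23.7) in females, so that the size of its change is uncertain. Further rises were those of C1qtnf3, a secreted relative of adiponectin (3.18 ± 0.29), Meg3, an imprinted noncoding RNA (2.87 ± 0.22), Mup3, a major urinary protein (2.69 ± 0.22), Sfrp1, a Wnt antagonist (2.40 ± 0.28), Adam8, a metalloprotease (2.39 ± 0.21), and Mfap4, a microfibril protein (2.28 ± 0.27). The probe set of Mup3 can bind related genes. Another probe set of Mfap4 gave 0.23, and other probe sets of Mmp12, Tnc and Meg3 gave 3.17, 2.76 and 1.38.

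The largest falls in females began with Ucp1, the uncoupling protein of brown fat (log2 -2.10 ± 0.53), with signals of 123 ± 110 in females and 619 ± 432 in males. Inmt (-1.52 ± 0.17), the histone gene H3c14 (-1.49 ± 0.27), Nr1d1, a repressor of the circadian clock (-1.24 ± 0.22), Krtdap (-1.21 ± 0.19), Actb (-1.21 ± 0.31), Spock2 (-1.11 ± 0.26), Hsd11b1, which regenerates active glucocorticoid (-1.07 ± 0.28), Mgst3 (-1.05 ± 0.15) and Tcap (-1.02 ± 0.25) followed. Other probe sets gave -0.65 for Ucp1, -0.45 for Spock2 and -0.16 for Mgst3. When single arrays were left out, Ucp1 (-2.45 to -1.63) failed to pass without 13 of them, Actb (lowest -1.35) without 12, Spock2 (-1.24 to -0.94) without 10, Hsd11b1 (-1.33 to -0.92) without 15 and Tcap (-1.12 to -0.85) without 13. Actb also failed to pass after quantile normalization (-1.17). Against vehicle Actb was -2.35, -0.56 and -1.58 at 1, 3 and 6 h, and -0.28, 0.28 and 0.09 at 12, 18 and 24 h. Antisense control levels were low on the female 1, 3 and 6 h arrays but among males only at 1 h. The fall of Actb in females therefore cannot be told apart from that technical measure. With 15 arrays all 10 passed, and larger falls included Pon1 (-2.14 ± 0.39), Nnat (-1.79 ± 0.14), Ephx1 (-1.56 ± 0.20), Cidea (-1.53 ± 0.16), Npr3 (-1.36 ± 0.16, and -0.43 and -0.57 by its other probe sets) and Sncg (-1.36 ± 0.13), while Ckap4 rose by 2.29. Lep was -0.87 ± 0.37 with 16 arrays (adjusted p from limma = 0.218) and fell by 1.19 ± 0.20 with 15 (0.00173). Adipoq (0.27), Pparg (0.27) and Fkbp5 (-0.45) did not pass (adjusted p from limma = 0.812, 0.798 and 0.118), nor did they with 15 arrays, where Adipoq (-0.20) and Pparg (-0.16) changed sign and Fkbp5 was -0.38 (0.165, 0.524 and 0.0681).

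**Figure D3:**
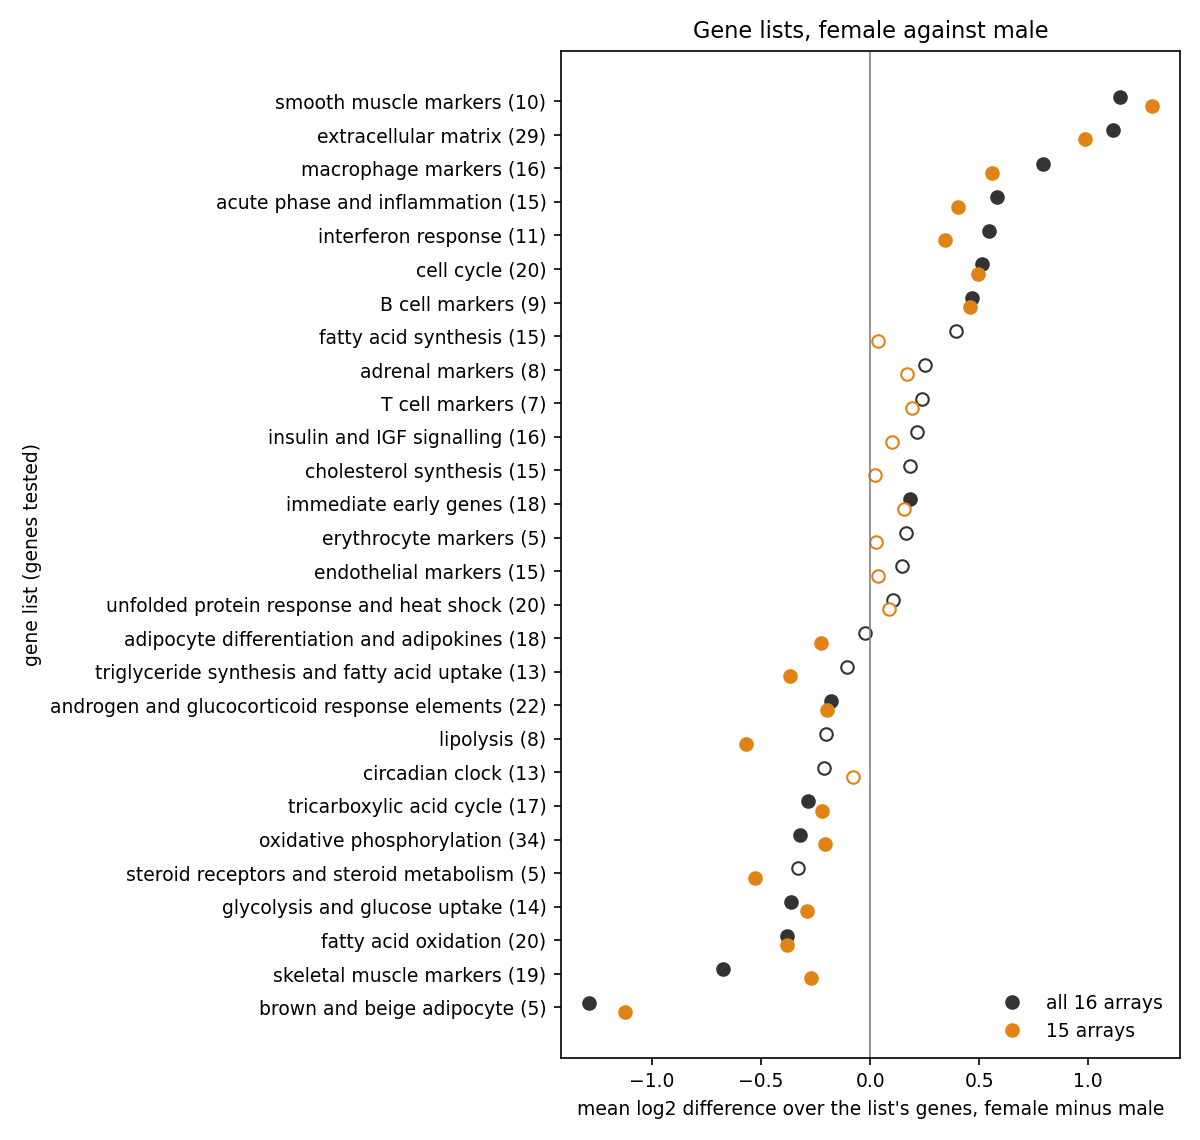
Mean log2 difference, female minus male, of the 28 tested gene lists with all 16 arrays (black) and with 15 arrays (orange); filled points had an adjusted p from camera under 0.05 and open points did not. The extracellular matrix list lies at 1.11 and 0.98, and the brown and beige adipocyte list at -1.29 and -1.13.

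Of 29 extracellular matrix genes, all had higher means in females, 18 rose over all genes and 21 adjusted over the list alone (mean 1.11). They included Col1a2, a chain of collagen I (2.13 ± 0.12), Eln, elastin (1.80 ± 0.15), and Lum, lumican (1.61 ± 0.13). Of 10 smooth muscle genes 7 rose, 8 adjusted over the list alone (mean 1.14), with Myh11, the smooth muscle myosin (1.97 ± 0.26), and Tagln, transgelin (1.68 ± 0.14). Of 20 cell cycle genes 6 rose, 12 adjusted over the list alone (mean 0.51), with Cdk1, the mitotic kinase (1.86 ± 0.27). Camera in limma gave an adjusted p of 7.29e-21, 1.597e-08 and 5.668e-07 to these lists. With an estimated correlation the adjusted p was 0.0574, 0.0165 and 0.0116. With 15 arrays their means were 0.98, 1.29 and 0.49, and the adjusted p with an estimated correlation was 0.0102 each.

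Immune lists were also higher in females by camera, without keeping the call with an estimated correlation. Of 16 macrophage genes 5 rose, 8 adjusted over the list alone (mean 0.79, adjusted p = 1.013e-07, and adjusted p = 0.343 with an estimated correlation), with Ctss, cathepsin S (1.53 ± 0.20), and Lgals3, galectin 3 (1.44). Of 15 acute phase genes 4 rose, 6 adjusted over the list alone (mean 0.58, adjusted p = 0.000256, and adjusted p = 0.297 with an estimated correlation), with Saa3, a serum amyloid (1.79). Of 11 interferon genes 1 rose (Ifit3, 0.84), 3 adjusted over the list alone (mean 0.54, adjusted p = 0.000991, and adjusted p = 0.464 with an estimated correlation). Of 9 B cell genes 1 rose (Jchain, 0.91), 4 adjusted over the list alone (mean 0.47, adjusted p = 0.00134, and adjusted p = 0.101 with an estimated correlation). Of 18 immediate early genes 3 rose, 4 adjusted over the list alone (mean 0.18, adjusted p = 0.0437, and adjusted p = 0.248 with an estimated correlation), and the list was not called without male vehicle replicate 2 (0.16, adjusted p = 0.141). Macrophage genes were low on that male array, and their mean was 0.56 without it, when 11 rose.

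Lists of oxidative metabolism ranked lower in females by camera, without keeping the call with an estimated correlation. Of 20 fatty acid oxidation genes 5 fell, 9 adjusted over the list alone (mean -0.38, adjusted p = 2.405e-08 by camera in limma, and adjusted p = 0.0546 with an estimated correlation). Acaa2 (-0.65) and Hadhb (-0.50), which act in mitochondrial beta-oxidation, were among them. Of 5 brown adipocyte genes 1 fell over all genes and 3 adjusted over the list alone (mean -1.29, adjusted p = 0.000848, and adjusted p = 0.0546 with an estimated correlation). Of 34 oxidative phosphorylation genes 1 fell (Cox7a2, -0.58), also 1 adjusted over the list alone (mean -0.32, adjusted p = 2.738e-08, and adjusted p = 0.368 with an estimated correlation). Of 17 tricarboxylic acid cycle genes 0 fell in limma, and 3 adjusted over the list alone (mean -0.29, adjusted p = 0.000228, and adjusted p = 0.333 with an estimated correlation). Glycolysis (14 genes, mean -0.36, adjusted p = 0.000687) and skeletal muscle genes (19 genes, mean -0.68, adjusted p = 0.000154) ranked lower with no member past the threshold, and the adjusted p with an estimated correlation was 0.101 and 0.518. Of the 22 hormone response element genes none passed, and Zbtb16 (-0.71) and Gadd45g (-0.47) fell adjusted over the list alone (mean -0.18, adjusted p = 0.00691, and adjusted p = 0.0574 with an estimated correlation). With 15 arrays 6 of the 22 fell, 11 adjusted over the list alone, and the list kept its call (mean -0.20, adjusted p = 0.00199 by camera, and adjusted p = 0.0461 with an estimated correlation). In the order given, 10 fatty acid oxidation, 4 brown adipocyte, 12 oxidative phosphorylation, 6 tricarboxylic acid cycle, 4 glycolysis and 6 skeletal muscle genes then fell in limma. The means of these lists were -0.38, -1.13, -0.21, -0.22, -0.29 and -0.27, and the adjusted p with an estimated correlation lay between 0.0669 and 0.583.

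With 15 arrays, 3 lists of fat cell function were called lower in females that were not called with 16. Of 8 lipolysis genes 7 fell over all genes and adjusted over the list alone (mean -0.57, adjusted p = 4.441e-06 by camera in limma, and 0.0476 with an estimated correlation), with Pnpla2, the first lipase of triglyceride breakdown (-0.71 ± 0.06), and Lipe (-0.82 ± 0.09). Of 13 triglyceride synthesis genes 6 fell, 8 adjusted over the list alone (mean -0.37, 5.33e-05, and 0.0265 with an estimated correlation), with Cidec, a lipid droplet protein (-0.86). Of 18 adipocyte genes 6 fell and 1 rose, 7 and 1 adjusted over the list alone (mean -0.23, 0.00244, and 0.0476 with an estimated correlation), with Cebpa (-0.33) and Rbp4 (-0.47). The steroid list was also called (mean -0.53, adjusted p = 0.00203, and adjusted p = 0.176 with an estimated correlation), in which 2 genes fell over all genes and 3 adjusted over the list alone.

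The 13 lists not called with 16 arrays had adjusted p between 0.0642 and 0.608 by camera. Their means were -0.33 for the steroid list (Hsd11b1 fell), 0.39 for fatty acid synthesis, -0.11 for triglyceride synthesis, -0.20 for lipolysis, 0.18 for cholesterol synthesis, -0.21 for the clock (Nr1d1 fell) and 0.22 for insulin and IGF signalling (2 rose, 1 fell). Further means were 0.11 for the unfolded protein response, 0.24 for T cells (Thy1 rose), 0.15 for endothelium, 0.25 for adrenal and 0.17 for erythrocyte genes. Adipocyte genes had a mean of -0.02 and a median of 0.03, and Dlk1, a marker of precursor cells, rose. With 15 arrays, signs differed for T cells (mean 0.19, median -0.01), fatty acid synthesis (mean 0.04, median -0.04, ranked down) and the clock (mean -0.08, median 0.00).

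All male arrays had brighter hybridization controls (mean log2 10.18 to 11.46) than all female arrays (8.76 to 9.96). These controls are RNAs added before hybridization, so that the sexes also differed in a technical measure. With the 4 vehicle arrays alone limma called 0 genes for female against male (206 at an unadjusted p under 0.05), and with the 12 DHT arrays alone 752.

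The sex difference of the DHT response was then tested as an interaction. No gene passed with 16 or 15 arrays in limma (365 and 163 at an unadjusted p under 0.05). The smallest p among genes with a more positive response in females were those of Smtn (3.37), Ly6d (2.05) and Mb (3.81), and with a more negative one those of Mmp9 (-2.22), Gtse1 (-1.73) and Mest (-1.69), with an adjusted p of 0.594 each. With 15 arrays these were 2.51, 2.17 and 2.04, and -2.22, -2.23 and -1.11. The muscle-rich array thus carried much of the value of Mb (3.81 to 2.04) and a smaller part of that of Smtn (3.37 to 2.51). Within males the mean response gave 1 gene with 16 arrays and 0 with 15 (1182 and 184 at an unadjusted p under 0.05), and within females 0 and 3 (64 and 172). The male gene was Gadd45g (1.64 ± 0.20), and the female genes were Fkbp5 (1.66 ± 0.20), Inmt (1.53 ± 0.16) and Mt2 (1.42 ± 0.19). The hormone list did not differ (mean -0.08, adjusted p = 0.958 by camera). Camera called 14 lists with 16 arrays and none of them with an estimated correlation. With 15 arrays it called skeletal muscle (0.83), which did not keep the call with an estimated correlation. The male baseline was then male vehicle replicate 1 alone, whose skeletal muscle level (median log2 0.75) was the highest of the 15 arrays. On simulated data with independent noise, the self-test recovered 10% of genes that differed by a log2 of 1 and 67% of those that differed by 2. Without male vehicle replicate 1 the count was 1917, since the muscle-rich array was then the lone male vehicle array.

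Male and female responses at matched times were finally compared across the 5686 genes. The mean correlation of matched times was 0.006, against -0.006 for unmatched times. Matched times ranged from -0.06 to 0.13 and unmatched times from -0.16 to 0.18. In an exact one-sided permutation test 242 of 720 pairings gave a mean as high (p = 0.336), and with 15 arrays 238 did (mean 0.020, p = 0.331). Genes are not independent replicates, and each sex's fold changes share its own vehicle arrays. Some pairings went with antisense control levels rather than time. With 15 arrays the male 1 h array gave 0.12, 0.10 and 0.13 with the female 1, 3 and 6 h arrays, all low in that level. It gave -0.13, -0.23 and 0.02 with female 12, 18 and 24 h. The male 6 h array, not low in it, also gave 0.05, 0.09 and 0.07 with female 1, 3 and 6 h. Such a structure may hide a shared time course, which was not tested.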

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

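The tests of muscle transcripts, of the 4 genes that rose with DHT and of the sexes were chosen only after the results were seen. So were the searches for arrays far from the others. The exception was the test with the hybridization controls as a covariate, although its use of 15 arrays was also chosen afterwards. The counts over other groupings of the arrays were planned.

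Values far from the rest of a group were searched in 57 tests, each of 1 quantity within the male, female or vehicle arrays. Of these, 10 were found, 7 of them in male vehicle replicate 2 and 3 in other arrays. Chance alone gives about 1 in 20 tests. The tests share arrays and are not independent, and several used measures by which male vehicle replicate 2 had already been singled out. Male vehicle replicate 2 had a median correlation with the other arrays of 0.675 (the nearest were 0.921 among males and 0.918 among vehicle arrays). Its median log2 level was 3.50 for skeletal muscle genes (nearest 0.75), -0.95 for adipocyte genes (0.07) and -2.26 for macrophage genes (-0.44). Its signal was 1946 for Adipoq (nearest 21143) and 100.03 for Pparg (992). Among the 8 female arrays, Xist was highest at 18 h (2200.2, nearest 1399) and Ucp1 at 3 h (367, nearest 174). Among the 4 vehicle arrays Ucp1 was highest in male vehicle replicate 1 (350.01, nearest 51.9). Higher Ucp1 signals occurred on male DHT arrays (up to 1422).

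The interaction test with 16 arrays called a sex difference in the mean DHT response of 14 lists. Of these, skeletal muscle alone was called with 15 arrays (0.83), when male vehicle replicate 1 alone set the male baseline. Female minus male, the means were 2.22 for skeletal muscle, 0.91 for smooth muscle, 0.52 for the clock, 0.33 for oxidative phosphorylation and 0.20 for the tricarboxylic acid cycle. They were -1.53 for fatty acid synthesis, -1.42 for lipolysis, -1.05 for triglyceride synthesis, -0.96 for macrophages, -0.90 for interferon response, -0.84 for adipocytes, -0.82 for cholesterol synthesis, -0.54 for endothelium and -0.52 for extracellular matrix. Their adjusted p from camera in limma lay between 4.011e-15 and 0.0470, and with an estimated correlation between 0.578 and 0.590. The array of male vehicle replicate 2 is 1 of the 2 that set the male baseline, and without it the means of lipolysis (0.066), oxidative phosphorylation (-0.16), the tricarboxylic acid cycle (-0.066) and the clock (-0.033) changed sign.

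Antisense control probe sets, which the comparisons did not use, reached a mean log2 level of 9.96 in the female 18 h array. Vehicle arrays lay between 7.64 and 9.14, and 2 DHT arrays lay above the highest of them. The arrays fell into separate levels, 6.38 to 6.75 (male 1 h and female 1, 3 and 6 h), 7.64 to 7.69 (the second vehicle array of each sex) and 8.62 to 9.96 (the other 10).

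The first pattern weighed was the muscle transcripts in male vehicle replicate 2, read from marker genes listed beforehand, of which Pvalb is also in the kidney list. Atp2a1 (37701), Myl1 (35497) and Tnnt3 (35005) had its highest signals among the muscle genes listed, and no sort or gate would have removed muscle. A minor admixture to fat would leave most fat transcripts in place, but 45 abundant adipocyte genes stood at a median of 16.8% of their level on the other male arrays (quartiles 7.24 and 36.3), and degraded RNA goes against a Gapdh 3' to 5' ratio of 0.957 (0.801 to 0.925 on the other arrays). A sample mostly or wholly of muscle may be a candidate explanation (Adipoq stood at 7.51% of its level on the other male arrays), but without a muscle array the share cannot be told apart. No biological explanation was tested, since the design gives none.

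The second pattern was the rise of Fkbp5, Mt2, Gadd45g and Errfi1. It is not owed to the muscle-rich array, since 4 of 4 genes passed without it, nor to the antisense levels as a whole, since the mean of the 4 was 1.22 ± 0.07 with that level as a covariate (1.25 ± 0.08 without) in 15 arrays. With all 16 arrays and the covariate Errfi1 (0.79) no longer passed. The mean of 0.89 ± 0.11 at 24 h would go against the injection itself as the whole cause there if the 24 h given for the vehicle arrays is the time since injection, but no label says so, and earlier times (1.44 ± 0.09 at 12 and 18 h) have no vehicle array of their own. A response to the injection therefore cannot be told apart from one to DHT, which may be the cause and stays a hypothesis. The list that holds these genes joins targets of androgen and of glucocorticoid response elements, so membership in it does not tell these hormones apart.

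The third pattern was the higher matrix and smooth muscle transcripts in females. With the hybridization control level as a covariate, in a model without time, the matrix list kept a difference of 1.06 ± 0.10 (0.98 ± 0.04 without). The levels of the sexes did not overlap. This goes against that measure as the cause only if the trend within each sex holds across the gap, which no array can show. A lower share of adipocytes in females, with all other cells in unchanged proportions, would raise endothelial and matrix genes alike. Endothelial minus matrix was -0.95 ± 0.09 with 15 arrays, where the endothelial list was at 0.04 ± 0.07, which goes against that form alone. A lower share together with unequal changes of other cells is not excluded. The adipocyte list was at -0.23 ± 0.02 and the macrophage list at 0.56 ± 0.06. Processing of the sexes at different times cannot be told apart from sex, since the highest female control level (9.96) lay below the lowest male one (10.18). A difference between the sexes in the cells or matrix of the depot may be the cause and was not tested.

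Other groupings of the same arrays were drawn 100 times for each count, the real one included. For DHT over all times 1 grouping gave as many genes (real 4, highest other 0), for the F test 1 (real 3, highest other 2), and for female against male 1 (real 327, highest other 22). The real grouping alone reached these counts, and 1 in 100 is the lowest share that 100 groupings can give. All these groupings held the muscle-rich array, which may keep other counts low by widening the spread. Chance is therefore not excluded for the DHT and F test counts. For late against early times (real 0, highest other 1) and for the sex difference of the response (real 0, highest other 52), all 100 groupings gave as many, which a real count of 0 makes certain, so that this says nothing about chance. For DHT over all times with 15 arrays 5 did (real 5, highest other 528), so that chance is not excluded there. Groupings with 528 and 443 genes took the male 3 h, female vehicle 1 and female 18 h arrays as vehicle, which points to a structure of the samples other than the treatment. These 3 arrays have the highest antisense levels of all (9.28, 9.14 and 9.96). With that level as a covariate Fkbp5, Mt2, Gadd45g and Errfi1 all passed in the real grouping, which is not a count over all genes. One with 67 genes took the male 1 h, female vehicle 2 and female 24 h arrays. One with 7 genes took the male 1 h, female 1 h and female 6 h arrays, which have low antisense levels. The mean of Fkbp5, Mt2, Gadd45g and Errfi1 was 1.22 with that level as a covariate. For female against male with 15 arrays the real grouping alone, of the 100, gave as many (real 943). The highest other, at 726, was the real grouping by sex with female vehicle replicate 1 alone moved.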

How the results depend on the processing

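Leaving out each array was planned, but reading the 15 arrays as a setting of their own, the antisense covariate and their combinations were chosen after the data were seen. Counts of genes stayed within 1.5 times their reported value with a pseudocount of 1 or 64, no filter, a filter at the 60th percentile and quantile normalization. Counts of lists, run with a pseudocount of 64, no filter and quantile normalization, did so too, and under these 3 settings the matched-time correlation kept its sign and did not pass. No paired analysis was possible because replicate numbers were given in accession order only. Low signals lie close to background, and changes of genes near the filter are the least certain. When an array of a time was left out, the array that remained was assumed to vary like the others. Except where said, the cause was not tested.

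The F test gave 0 genes in limma with all probe sets tested separately (86 at an unadjusted p under 0.05), without a trend (63), and with separate means (23). Separate means, with 2 residual degrees of freedom, gave 0 genes at 3, 6 and 12 h (22, 23 and 33 unadjusted), and the 6 times as replicates 0 over all times (638). For female against male the 4 vehicle arrays gave 0 (206), which fewer samples can cause by construction, and the 12 DHT arrays 752. With the estimated correlation, list tests gave 1 call each at 1, 3, 6, 12 and 18 h and over all times, 0 at 24 h (1 unadjusted), 2 for female against male and 0 for the sex difference of the response (1 unadjusted). The matched-time correlation was -0.019 without the 18 h time. Between the sexes, Lep (0.53) and Npr3 (0.54) reversed in the vehicle arrays alone, and Adipoq (-0.19) and Pparg (-0.26) in the DHT arrays alone. Of the 2 male vehicle arrays 1 is the muscle-rich array, where Lep had a signal of 715 (4259 ± 1157, SD, n = 7, on the other male arrays).

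Without male vehicle replicate 2, values reversed for DHT over all times in 8 results, given here with the opposite end of the range over all left-out arrays: Lep (-0.038 to 0.92), Adipoq (-0.039 to 1.33), fatty acid synthesis (-0.040 to 0.97), triglyceride synthesis (-0.070 to 0.69), lipolysis (-0.028 to 1.05), oxidative phosphorylation (0.019, lowest -0.34), interferon (-0.046 to 0.52) and macrophages (-0.045 to 0.65). They reversed between the sexes in Adipoq (-0.20 to 0.49) and Pparg (-0.16 to 0.41), and for the sex difference of the response in lipolysis (0.066, lowest -2.90), oxidative phosphorylation (-0.16 to 0.82), the tricarboxylic acid cycle (-0.066 to 0.47) and the clock (-0.033 to 1.06). The matched-time correlation was -0.019 without the male or female 18 h array and -0.046 without female vehicle replicate 2.

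The antisense covariate gave an F test of 0 genes (89 unadjusted in limma), list calls of 4 at 18 h, 5 at 24 h and 6 for late against early, and -0.17 for Hp late against early. Without the muscle-rich array and with the covariate, genes numbered 5 at 12 h, 2 at 18 h, 2 at 24 h, 1 for late against early and 1048 for female against male. List calls were then 4, 1, 1, 2, 3 and 4 at the 6 times, 3 over all times, 1 for late against early and 2 for the sex difference of the response. Values reversed for DHT in Lep (-0.16), Pparg (-0.025), fatty acid synthesis (-0.043), triglyceride synthesis (-0.086), lipolysis (-0.022), interferon (-0.075) and macrophages (-0.041), and between the sexes in Adipoq (-0.10) and Pparg (-0.20). For the sex difference of the response they reversed in lipolysis (0.072), oxidative phosphorylation (-0.19), the tricarboxylic acid cycle (-0.10), the clock (-0.039) and, for macrophage markers, sex difference of the DHT response, to 0.000555. Without the muscle-rich array, separate means gave 2 genes at 1 h, 0 at 3 h (61 unadjusted in limma) and 1 at 6 h, and the 6 times as replicates gave 0 over all times (174), with Lep at -0.038 and Adipoq at -0.039.

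Leaving out each array gave 0 to 1 genes at 1, 3 and 24 h, 0 to 5 at 6 h, 0 to 4 at 12 h, 0 to 2 at 18 h, 2 to 5 over all times, 0 to 2 for late against early, 197 to 943 between the sexes, 0 to 5 for the F test and 0 to 1917 for the sex difference of the response. The last was reached without male vehicle replicate 1, which leaves the muscle-rich array as the lone male vehicle. List calls ranged from 2 to 15 at 1, 3 and 12 h, 2 to 16 at 6 h, 5 to 13 at 18 h, 4 to 14 at 24 h, 2 to 16 over all times, 0 to 4 for late against early, 14 to 18 between the sexes and 1 to 16 for the sex difference of the response. The matched-time correlation ranged from -0.046 to 0.063. Of other values, 132 were unchanged in call with a pseudocount of 64, 130 with quantile normalization (2 weaker) and 126 with no filter (6 weaker). The estimated correlation left 10 and weakened 40, and leaving out male vehicle replicate 2 left 86, weakened 16, strengthened 16 and reversed 14.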

Other observations

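Gene families, genes high on single arrays, clock genes and the time courses of Inmt, Lrg1 and Hp were examined only after the data were seen. Among 42 families formed by gene symbol, collagen genes ranked first between the sexes by camera with 15 arrays and the correlation of 0.01. With an estimated correlation the immunoglobulin kappa variable genes ranked first. Of 20 tested collagen genes 12 rose in females (mean 0.70, adjusted p = 1.452e-08 by camera in limma, and adjusted p = 0.0911 with an estimated correlation). Of 11 immunoglobulin kappa variable genes, which antibody-producing cells express, 6 rose in females (mean 0.63, adjusted p = 2.656e-05, and adjusted p = 0.0597 with an estimated correlation). Of 37 genes of the large mitochondrial ribosomal subunit 2 fell (mean -0.17, adjusted p = 0.000953, and adjusted p = 0.678 with an estimated correlation). Late against early, the kappa genes (0.20), 14 cytochrome P450 genes (0.22) and 18 keratin genes (0.18) ranked higher (adjusted p = 0.0109, 0.0121 and 0.0121 by camera, and adjusted p = 0.192, 0.192 and 0.843 with an estimated correlation).

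The female 12 h array had high signals of digestive enzymes and secreted proteins that the exocrine pancreas makes. On it 13 genes lay at least 2-fold above each of the other 15 arrays, against 409 on male vehicle replicate 2. Cela2a, a pancreatic elastase, had a signal of 18797.5 there and 254 ± 106 (SD, n = 15) elsewhere, Cel, a bile salt-dependent lipase, 12656 and 513 ± 182, and Clps, the cofactor of pancreatic lipase, 6081 and 150.3 ± 133. Ctrb1, chymotrypsinogen, had 28553 there and at most 3825 elsewhere. No list of pancreas genes had been written beforehand, and no explanation was tested. Without this array limma called 0 genes at 12 h (78 at an unadjusted p under 0.05).

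The acute phase genes Lrg1 and Hp were singled out because they passed late against early with 15 arrays, and their courses were not tested against those of other genes. Early and late arrays also differed in antisense control levels (6.38 to 6.75 on 4 of 6 early arrays, 8.68 to 9.96 late). With that level as a covariate and 15 arrays, late minus early was 0.93 ± 0.12 for Lrg1, which passed, and 0.68 ± 0.10 for Hp, which did not (0.81 ± 0.09 and 0.63 ± 0.07 without it). With 15 arrays Lrg1 was at -0.29, -0.06, 0.29, 0.51, 0.78 and 1.07 (each ± 0.14) at the 6 times in order, and Hp at -0.48, -0.05, 0.14, 0.21, 0.53 and 0.77 (each ± 0.11). Inmt was at -0.12, 0.68, 1.17, 1.64, 1.74 and 1.48 (each ± 0.30) with 16 arrays and did not pass at any time there. Clock genes varied over times with 15 arrays by 0.92 for Nr1d1, 0.71 for Nr1d2, 0.95 for Per1 and 0.52 for Per3 on the log2 scale. The largest difference in the mean of these 4 genes was 0.34 ± 0.16, between 12 and 24 h. Mesothelial markers (3 genes) and kidney markers (2 genes) were too few to test, with medians of 0.14 and -0.42 for DHT over all times and of 0.13 and -0.37 for female against male.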
